A study of Arabidopsis thaliana with 10 samples.

How the data were processed

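RNA from 3 groups of 3 replicates was measured on 10 single-colour Agilent arrays: grafts, ungrafted parts (scions and stocks mixed) and intact seedlings. Per the labels' protocols the RNA was extracted with Trizol and labelled with Cy3. Intact replicate 3 was hybridised to 2 arrays, which were averaged, so 9 RNA samples enter each test. The arrays lay on 3 slides: slide 1 held grafts 1 and ungrafted 1 and was scanned on a day of its own, slide 2 held grafts 2, ungrafted 2 and intact 1 and 2, and slide 3 held grafts 3, ungrafted 3 and intact 3. Sample names such as grafts 1 give the group and the replicate.

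Per the file headers the spot intensity values were extracted with Agilent Feature Extraction 10.5.1.1, and the processed signal is a background-corrected intensity. The deposited value table is in log2 units and was made with R 2.10.0 per the submitters' processing notes. Its columns hold the same sorted values to within 0.000859, with a median of 10.3 in each, as quantile normalization gives, and it served as an alternative source. Of 45220 spots per array 43803 were no controls, and they stood for 43603 probes. Of these, 244 were left out because a spot was flagged on at least 1 array. No spot was saturated. One locus was named for 35642 probes, several loci for 454 and none for 7263. Probes without a single locus were tested apart.

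The log2 of the processed signal minus the array's 75th percentile over probes other than controls was used. Of the probes of a locus the one with the highest mean was taken, among 26047 loci, and a locus was tested if its probe was well above background on every replicate of at least 1 group, which left 21265. Spots well above background made up 74.4% to 80.1% of an array, and dim genes are limited by this. A gene with a group not above background on any array is given as a bound (at least N-fold), and where some arrays of a group measured it their number is given. Linear models over the 3 groups were fitted with limma 3.58.1 in R 4.3.3 (statmod 1.5.0, data.table in version 1.17.8), with moderated t tests and Benjamini-Hochberg adjustment, and genes with adjusted p below 0.05 are called changed. There were 6 residual degrees of freedom, with a prior of 2.93, and the median SE was 0.13. The median SD between replicates was 0.11 in grafts, 0.12 in ungrafted parts and 0.18 in intact seedlings. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

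Graft-specific genes follow the order of steps in the series design: adjusted p below 0.05 between grafts and intact seedlings, and below 0.05 between grafts and ungrafted parts with adjustment over the first set alone, in the same direction. The design states no threshold. Similarity was taken as correlations and covariance across genes, beside 100 simulations of unchanged groups. Gene lists, 35 with 508 members, were fixed before the values were seen and tested with camera with a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry. Not used were XTH17, which is not on the array, and 13 members whose names could not be paired with a locus in the reference.

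Genes were named by a rule written before the values were seen. Per comparison it takes the 6 largest rises and 6 largest falls past the test with no overlap between groups, among genes above background on at least 1 array of each group compared (likewise for graft-specific genes, against ungrafted parts, with all 3 groups), up to 4 members with the lowest p of each list described, and genes always named, among them ALF4, ANAC071, RAP2.6L, WIND1, ERF115, GH3.3, LBD16, JAZ10, VSP2, XTH20 and HCA2. Results for some genes that the rule takes are not reported here. Lists described are those past the test and 8 others whatever their test gives. The lists of organ and cell type markers are described as gene lists, and no cell type is called from them.

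RNA quality was compared through 3209 loci whose probes lie 600 to 5000 bases apart, from the differences between upstream and downstream probe. Of genes changed between grafts and intact seedlings that were measured at the downstream probe, the upstream probe of 532 of 544 rises and 535 of 601 falls moved the same way. Of those measured at the upstream probe, the downstream probe of 39 of 47 rises and 11 of 16 falls did. Between grafts and ungrafted parts these were 25 of 26 and 19 of 21, and 3 of 3 rises. Whether equal numbers pair samples was checked from the correlation of deviations from group means. For grafts and ungrafted parts, which share slides, it was 0.18, 0.34 and 0.39 for numbers 1, 2 and 3, and a replicate block was therefore tried and gave 768 changed genes against 622.

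The procedure was tested on 21265 simulated genes, 200 changed at 4 fold sizes, 50 each. With grafts changed 4.92% of calls against intact seedlings were false and 3.37% against ungrafted parts. With ungrafted parts changed, 4.79% of calls against intact seedlings were false, and 7.73% between grafts and ungrafted parts, where 50.0%, 88.0%, 98.0% and all of the genes changed 1.5-fold, 2-fold, 4-fold and 8-fold were found. With intact seedlings changed 5.21% and 2.72% were false against grafts and ungrafted parts, and 58.0% and 50.0% of genes changed 1.5-fold were found. A shifted list was called, and no other list, each time it was simulated. The simulated genes varied independently of each other, so this does not test false calls of lists whose members vary together.

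Alternatives set before the data were examined covered background correction with normexp (offset 50) and quantile normalization, the array median in place of the 75th percentile, the deposited table, filters on dim probes, other ways from probes to genes, thresholds (2-fold, adjusted p below 0.01), either array of intact 3, replicate number or slide as a block, fits of 2 groups alone, a trended robust fit, and leaving out each replicate. An RNA quality covariate and the removal of slide 1 were chosen after seeing the data. Confidence intervals are 95% from 2000 bootstrap draws. The 10 splits of 3 against 3 samples give a lowest share of 0.1.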

Results

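RNA was measured in 3 groups of Arabidopsis thaliana Col-0, the common laboratory strain, 22 to 26 hours after 4-day-old seedlings had been cut. Grafts were cut seedlings whose scion (the shoot part) and stock (the root part) had been put back together. Ungrafted parts were a mixture of scions and stocks kept apart after the same cut, and intact seedlings were left uncut. Each group had 3 replicates, and the 2 arrays of intact replicate 3 were averaged. The 75th percentile of the signal lay between 6482 and 8074 in the 10 arrays. The 3 samples per group limit the precision. The first principal component held 76.1% of the variance across the 21265 genes tested and separated intact seedlings from both cut groups, and the second held 8.77%. Intact replicate 1 differed from intact replicates 2 and 3 by a median absolute log2 difference of 0.25 each, against 0.13 between replicates 2 and 3 and 0.05 between the 2 arrays of replicate 3.

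The balance of 5' and 3' signal, used here as a measure of RNA quality, differed between samples. In 3209 genes with probes 600 to 5000 bases apart, upstream minus downstream signal was taken relative to its mean over the samples. A low value marks a relative loss of 5' signal. The median was 0.20, 0.02 and 0.17 in grafts 1, 2 and 3, and -0.15, 0.02 and -0.18 in ungrafted parts 1, 2 and 3. In intact replicates 1, 2 and 3 it was -0.37, 0.21 and 0.10. Grafts and ungrafted parts therefore stood 0.02 against 0.02 on slide 2, but apart on slides 1 and 3.

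**Figure D1:**
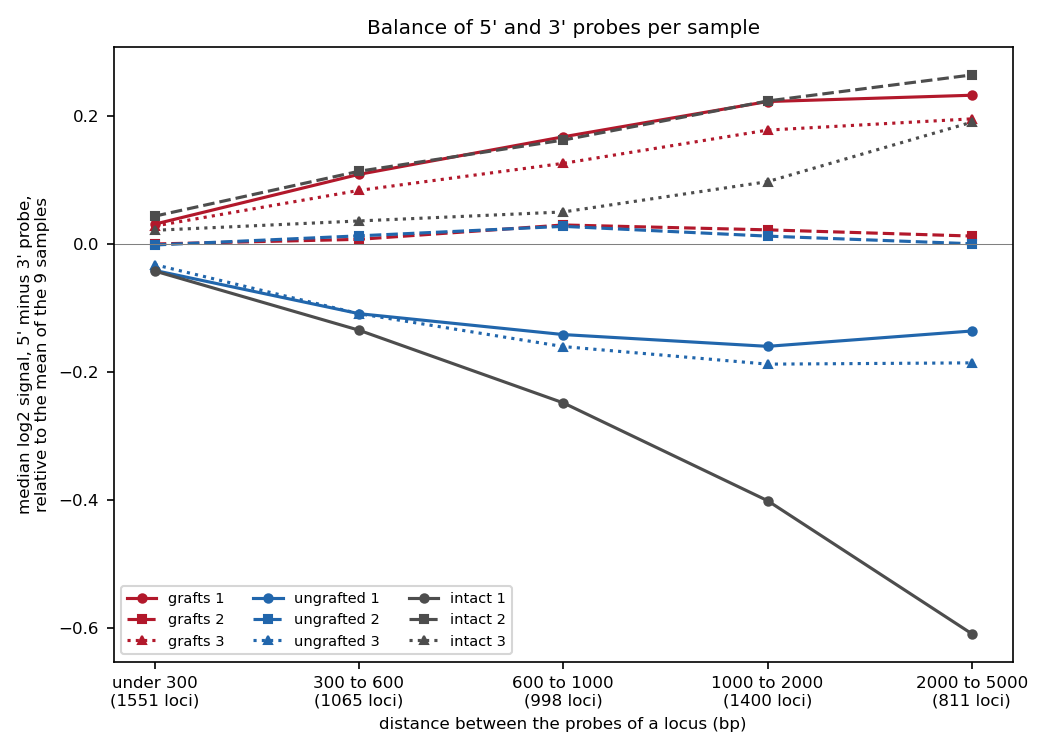
Median difference between the upstream and the downstream probe of a gene, in log2 units relative to the mean of the 9 samples, for gene sets by the distance between the probes, with 1 line or marker per sample and a colour per group. Intact replicate 1 reaches -0.61 for the largest distances, and graft and ungrafted samples part in replicates 1 and 3 but not in replicate 2.

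The first comparison, grafts against intact seedlings, takes cutting and rejoining together. Genes of anthocyanin synthesis, which makes the red pigments of stressed seedlings, were among the largest rises: DFR (7.81 ± 0.37) and LDOX (7.28 ± 0.3, above background on 3 of 4 intact arrays), both enzymes of the pathway, and PAP1 (7.81 ± 0.57, above background on 1 of 4 intact arrays), the MYB factor that activates it. Values are log2 differences ± SE with n = 3 samples per group. The other large rises were LTP4 (9.45 ± 0.72, above background on 1 of 4 intact arrays), a lipid transfer protein gene induced by water deficit, AT1G80130 (7.44 ± 0.22) and AT1G03940 (6.93 ± 0.48, above background on 1 of 4 intact arrays). Ranks here and in the next comparisons are among genes above background on at least 1 array of each group compared. The deepest such falls were AT1G52060 (-6.9 ± 0.55), AT2G39040 (-6.61 ± 0.35, above background on 1 of 3 grafts arrays) and AT2G38600 (-5.53 ± 0.41), followed by AT4G25250 (-5.48 ± 0.41, above background on 1 of 3 grafts arrays), RALFL27 (-5.45 ± 0.34) and AT1G19900 (-5.45 ± 0.29). For these 12 genes limma's adjusted p ran from 2.00e-07 to 1.54e-05, and the 3 samples of each group did not overlap. The probes of LTP4 (AT5G59310) and DFR (AT5G42800) lie on chromosome 5 at 23942912 to 23942971 and 17181588 to 17181647, in the build ath1:Jan2004 named by the array files.

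Metabolic and water-deficit genes rose as groups. For each list of genes fixed before the data were examined, the median log2 difference of its members is given, with the lowest and highest of its medians within each slide that held both groups and with slide as a block in square brackets. The list p is camera's, adjusted over 35 lists, with its preset correlation and then with an estimated one. Of 10 anthocyanin genes 8 rose (8 adjusted over the list alone), including UF3GT (6.85 ± 0.35) and TT8 (4.85 ± 0.26). Anthocyanin genes had median 6.02 [5.63 to 6.61], adjusted p = 3.29e-06, and 0.228 with an estimated correlation. With PAP2, above background in no intact array, set at its bound of at least 13.6-fold, the anthocyanin median was 5.67. All 6 sugar accumulation genes rose (6 adjusted over the list), among them GBSS1 (4.88 ± 0.15) of starch synthesis, BAM5 (5.66 ± 0.31, above background on 2 of 4 intact arrays), a beta-amylase, and APL3 (3.87 ± 0.17) and TPS5 (2.5 ± 0.16). Sugar accumulation genes had median 4.37 [4.18 to 4.5], adjusted p = 3.29e-06, and 0.228 with an estimated correlation. Of 20 genes of abscisic acid and water deficit 15 rose (16 adjusted over the list), such as LTP3 (6.16 ± 0.35), COR15A (6.12 ± 0.39) and COR15B (3.75 ± 0.24) and the proline synthesis gene P5CS1 (2.57 ± 0.16). These water deficit genes had median 2.1 [1.8 to 2.09], adjusted p = 8.39e-08, and 0.228 with an estimated correlation. Of 27 jasmonate genes, which act in the wound hormone pathway, 16 rose and 1 fell (18 adjusted over the list). Jasmonate genes had median 0.68 [0.84 to 1.3], adjusted p = 1.37e-05, and 0.302 with an estimated correlation. The jasmonate synthesis genes LOX2 (3.0 ± 0.18), AOC1 (2.84 ± 0.18), AOC2 (1.93 ± 0.16) and AOS (1.7 ± 0.08) were among them, as was the storage protein gene VSP2 (3.04 ± 0.28), while the repressor gene JAZ10 measured 0.51 ± 0.2 (adjusted p = 0.0623). Of 16 salicylate genes 9 rose and 1 fell (10 adjusted over the list). Salicylate genes had median 0.49 [0.34 to 0.5], adjusted p = 0.0324, and 0.476 with an estimated correlation. Those that rose included PR2 (3.02 ± 0.4), WRKY70 (1.22 ± 0.24) and WRKY62 (0.99 ± 0.16, above background on 2 of 3 grafts arrays and 1 of 4 intact arrays), and the member that fell was EDS5 (-0.63 ± 0.08). Of 20 glucosinolate and camalexin genes, which make defence compounds, 13 rose and 2 fell (16 adjusted over the list). Glucosinolate genes had median 0.45 [0.43 to 0.57], adjusted p = 0.00618, and 0.302 with an estimated correlation. Examples are CYP71A13 (2.16 ± 0.19), CYP79F1 (2.1 ± 0.23), MYB29 (1.55 ± 0.18) and MAM1 (0.88 ± 0.1).

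Wound and vascular lists were called higher as well. ANAC071, a transcription factor gene needed for cut stems to reunite, rose by 4.32 ± 0.13 on the log2 scale (adjusted p = 2.00e-07). Of the 17 genes of wound regeneration and tissue reunion 13 rose and 2 fell (15 adjusted over the list). Wound genes had median 0.57 [0.61 to 0.86], adjusted p = 1.08e-04, and 0.228 with an estimated correlation. Those that rose included PLT7 (1.94 ± 0.14, above background on 2 of 4 intact arrays) and WOX11 (1.8 ± 0.15, above background on 3 of 4 intact arrays), the vascular Dof factor gene HCA2 (0.88 ± 0.13) and, with small changes, RAP2.6L (0.5 ± 0.14) and WIND1 (0.44 ± 0.13), while the xyloglucan-modifying XTH20 (-1.39 ± 0.11) was lower. ERF115, a regeneration factor gene not well above background in intact seedlings, was at least 2.76-fold higher (adjusted p = 8.47e-05). Of 13 xylem and secondary wall genes 6 rose and 1 fell (7 adjusted over the list), such as MYB83 (1.0 ± 0.12), MYB46 (0.52 ± 0.09), VND7 (0.66 ± 0.14) and CESA8 (0.57 ± 0.13). Xylem genes had median 0.34 [0.24 to 0.48], adjusted p = 0.0228, and 0.416 with an estimated correlation. Of 9 cambium genes 5 rose (5 adjusted over the list), such as CLE44 (1.26 ± 0.18), CLE41 (1.11 ± 0.2), MP (0.74 ± 0.12) and LHW (0.61 ± 0.09). Cambium genes had median 0.56 [0.52 to 0.58], adjusted p = 0.0246, and 0.284 with an estimated correlation. Of 9 phloem genes 5 rose and 1 fell (6 adjusted over the list). Phloem genes had median 0.32 [0.37 to 0.78], adjusted p = 0.0480, and 0.360 with an estimated correlation. PP2-A1 (1.24 ± 0.09), APL (0.66 ± 0.09) and NEN4 (0.68 ± 0.14) rose and SEOR1 (-0.3 ± 0.09) fell. Of 31 cell cycle genes 4 rose and 1 fell (median 0.15 [0.21 to 0.22], 4 adjusted over the list, adjusted p = 0.156), with rises in TSO2 (1.01 ± 0.16), CYCD3;1 (0.76 ± 0.12) and RNR2A (0.6 ± 0.11) and a fall in CDC6 (-1.91 ± 0.12). ALF4, needed for lateral roots to form, rose by 0.31 ± 0.08 (adjusted p = 0.0152).

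Without single samples some of these calls ended, as adjusted p values in parentheses show. The salicylate list lost its call without grafts 1 (0.0682) or intact 2 (0.0685), with 0.0106 to 0.0685 over its alternatives. The phloem list lost it without grafts 3 (0.0884), ungrafted 1 (0.0508) or intact 1 (0.0920), with 0.0303 to 0.0920 over its alternatives. WIND1 and SEOR1 lost their calls with slide as a block. WIND1 also lost its call without grafts 2 (0.0565), grafts 3 (0.0771), intact 2 (0.0759) or intact 3 (0.0538), with 0.00122 to 0.0771 over its alternatives, and SEOR1 without grafts 1 (0.0839), grafts 2 (0.0907), intact 2 (0.0745) or intact 3 (0.0681), with 0.0115 to 0.127 over its alternatives. ALF4 lost it without grafts 2 (0.0565) or intact 3 (0.0547), with 0.0122 to 0.0565 over its alternatives, and RAP2.6L without grafts 2 (0.0616), with 0.0104 to 0.0616 over its alternatives. JAZ10 passed the test without grafts 1 (0.0416) or intact 1 (0.00430), with the mean of its probes (0.0127) or with the 5' measure as a covariate (0.00227), with 0.00227 to 0.179 over its alternatives.

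Lower in grafts than in intact seedlings were cytokinin, nitrate, gibberellin and root genes. Of 18 cytokinin genes 16 fell and 1 rose (17 adjusted over the list). Cytokinin genes had median -0.96 [-0.96 to -0.91], adjusted p = 2.96e-05, and 0.228 with an estimated correlation. The synthesis genes CYP735A1 (-1.94 ± 0.14), CYP735A2 (-1.74 ± 0.15) and IPT5 (-1.88 ± 0.18) and the response regulator gene ARR15 (-1.98 ± 0.2) fell. All 9 nitrate response genes fell (9 adjusted over the list), including the transporter genes NRT2.1 (-3.9 ± 0.22) and NRT1.1 (-0.74 ± 0.12), the nitrate reductase gene NIA1 (-2.64 ± 0.18) and LBD39 (-1.47 ± 0.14). Nitrate genes had median -0.91 [-1.04 to -0.65], adjusted p = 9.38e-05, and 0.228 with an estimated correlation. Of 12 gibberellin genes 6 fell and 1 rose (9 adjusted over the list). Gibberellin genes had median -0.92 [-1.06 to -0.86], adjusted p = 0.0114, and 0.228 with an estimated correlation. Those that fell included GASA1 (-2.19 ± 0.16), GA3OX2 (-2.24 ± 0.34), GA20OX3 (-1.58 ± 0.26) and GA2OX6 (-1.55 ± 0.22). Of 11 hypoxia genes 9 fell and 1 rose (10 adjusted over the list), such as SUS4 (-2.36 ± 0.08), PCO1 (-2.1 ± 0.15), LBD41 (-1.71 ± 0.14) and PDC1 (-1.36 ± 0.08). Hypoxia genes had median -0.94 [-1.02 to -0.97], adjusted p = 0.00164, and 0.228 with an estimated correlation. With HRE2, above background in no graft, at its bound, the hypoxia median was -0.86. Of 10 sugar depletion genes 7 fell and 1 rose (8 adjusted over the list). Sugar depletion genes had median -0.97 [-1.11 to -0.93], adjusted p = 0.00788, and 0.416 with an estimated correlation. ASN1 (-2.13 ± 0.22), TPS11 (-1.48 ± 0.13) and TPS9 (-1.07 ± 0.1) fell and BGLU30, a dark-induced beta-glucosidase gene, rose (3.07 ± 0.33).

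Of 23 ethylene and ERF genes 12 fell and 3 rose (15 adjusted over the list). Ethylene genes had median -0.63 [-0.63 to -0.46], adjusted p = 0.0480, and 0.364 with an estimated correlation. Those that fell included PDF1.2a (-2.82 ± 0.49, above background on 2 of 3 grafts arrays), RAP2.6 (-2.14 ± 0.27) and ACO1 (-1.28 ± 0.1), and ERF2 (2.52 ± 0.14) was among those that rose. The ethylene list lost its call without grafts 1 (0.0591), grafts 3 (0.0602) or ungrafted 1 (0.0508), with 0.0237 to 0.0924 over its alternatives. Of 11 phosphate starvation genes 7 rose and 2 fell (9 adjusted over the list). Phosphate genes had median 0.73 [0.72 to 0.78], adjusted p = 0.0452, and 0.360 with an estimated correlation. PAP17 (2.9 ± 0.29), SPX3 (1.4 ± 0.21) and MGD2 (0.83 ± 0.1) rose and the ribonuclease gene RNS1 (-1.71 ± 0.2) fell. The phosphate list lost its call without grafts 2 (0.0533), grafts 3 (0.0602), intact 1 (0.0596) or intact 2 (0.0554), with 0.0301 to 0.0758 over its alternatives. With quantile normalization the ethylene (0.0564) and phosphate (0.0615) lists did not pass either. Of 29 cell wall loosening genes 14 fell and 5 rose (21 adjusted over the list). Cell wall genes had median -0.66 [-0.78 to -0.57], adjusted p = 0.00943, and 0.284 with an estimated correlation. The expansin gene EXPA17 (-4.32 ± 0.11) and XTH18 (-2.42 ± 0.19) fell and EXPA3 (1.17 ± 0.09) rose. Of 9 suberin genes 7 fell and 1 rose (9 adjusted over the list), such as FAR5 (-2.11 ± 0.11), ASFT (-1.58 ± 0.18), CYP86B1 (-1.4 ± 0.15) and CYP86A1 (-1.39 ± 0.15). Suberin genes had median -1.17 [-1.22 to -1.14], adjusted p = 0.00140, and 0.284 with an estimated correlation.

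Markers of root cell types were lower in grafts. All 8 root hair genes fell (8 adjusted over the list), including MRH6 (-3.31 ± 0.16), COBL9 (-2.95 ± 0.16), PRP3 (-2.55 ± 0.15) and LRX1 (-2.28 ± 0.13). Root hair genes had median -2.41 [-2.59 to -2.27], adjusted p = 2.44e-06, and 0.228 with an estimated correlation. Of 7 root endodermis genes 6 fell (6 adjusted over the list), with the Casparian strip genes CASP1 (-2.03 ± 0.2), CASP2 (-1.95 ± 0.21) and CASP4 (-1.54 ± 0.14). Endodermis genes had median -1.54 [-1.57 to -1.31], adjusted p = 0.00164, and 0.309 with an estimated correlation. All 7 root abundant genes fell (7 adjusted over the list), such as the aquaporin genes TIP2;3 (-3.87 ± 0.31) and TIP4;1 (-2.72 ± 0.14) and the phosphate transporter gene PHT1;1 (-1.25 ± 0.15). Root abundant genes had median -1.25 [-1.41 to -1.14], adjusted p = 8.06e-05, and 0.228 with an estimated correlation. NRT2.1 belongs to this list as well as to nitrate response. Of 8 guard cell genes 5 rose (5 adjusted over the list), among them MUTE (1.23 ± 0.19), EPF2 (1.0 ± 0.24), SPCH (0.55 ± 0.12) and KAT1 (0.5 ± 0.08). Guard cell genes had median 0.52 [0.51 to 0.56], adjusted p = 0.0270, and 0.302 with an estimated correlation. Intact replicate 1, with the lowest 5' signal, is in the reference group of all of these shifts.

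Auxin genes went both ways. Of 24 auxin response genes 4 rose and 4 fell (median 0.06 [-0.21 to 0.02], 8 adjusted over the list, adjusted p = 0.896), with a mean of -0.07 against the positive median. IAA20 (1.42 ± 0.16), GH3.5 (1.09 ± 0.21) and LBD17 (1.06 ± 0.14) rose. LBD29, not well above background in grafts, was at least 1.43-fold lower (adjusted p = 0.00249), and GH3.3 (-0.89 ± 0.35) and LBD16 (0.63 ± 0.37) did not pass. GH3.3 passed the test in 6 of 27 alternatives, without grafts 1 (0.0425) or intact 2 (0.0260) and with slide (0.0439) or replicate number (0.00229) as a block among them, with 0.00229 to 0.195 over its alternatives. Of 25 genes of auxin synthesis and transport 5 rose and 6 fell (median -0.01 [-0.2 to -0.07], 11 adjusted over the list, adjusted p = 0.924). PID (0.93 ± 0.09) rose, while PIN2 (-1.7 ± 0.2), ABCB4 (-1.45 ± 0.12) and YUC3 (-1.22 ± 0.18) fell. Of the lists not past the test, 6 of 15 phenylpropanoid genes fell and 2 rose (median -0.33 [-0.41 to -0.27], 12 adjusted over the list, adjusted p = 0.140), and 3 of 5 root meristem genes fell (median -1.05 [-1.01 to -0.64], 4 adjusted over the list, adjusted p = 0.0642). Of 26 photosynthesis genes 4 fell and 1 rose (median -0.1 [-0.14 to 0.05], 4 adjusted over the list, adjusted p = 0.189), and of 7 shoot apex genes 3 rose and 1 fell (median 0.33 [0.24 to 0.86], 4 adjusted over the list, adjusted p = 0.102). Of 6 plasmodesmata and callose genes 2 rose and 1 fell (median -0.1 [-0.11 to -0.09], 3 adjusted over the list, adjusted p = 0.924), with a positive mean and test. Of 10 iron deficiency genes 2 rose and 2 fell (median 0.11 [-0.22 to 0.07], 4 adjusted over the list, adjusted p = 0.924), with a mean of -0.61 and a test towards lower values. Heat shock and oxidative stress genes numbered 4 up and 3 down of 10 (median 0.11 [0.11 to 0.41], 7 adjusted over the list, adjusted p = 0.924), clock genes 5 up and 5 down of 12 (median -0.16 [-0.19 to 0.01], 11 adjusted over the list, adjusted p = 0.896, with a positive mean and test), and 1 of 6 reference genes fell (median -0.02 [-0.04 to 0.09], 1 adjusted over the list, adjusted p = 0.821). Without grafts 2 (0.0455) or intact 3 (0.0316) or with no filter on dim probes (0.0449) the root meristem list passed, as did cell cycle with slide as a block (0.0163).

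In numbers, 9038 of 21265 genes changed between grafts and intact seedlings by limma (4254 higher and 4784 lower), of which 1230 and 1901 did so by 2-fold or more. The 3 values of each group did not overlap for 52.7% of the genes, where chance gives 10%. Camera called 23 lists with its preset correlation. No list was called with an estimated correlation, where 6 had an unadjusted p under 0.05, while fry, which tests a list without setting it against other genes, called 27. In simulated data with grafts changed, 38.0% of genes changed 1.5-fold, 88.0% of those changed 2-fold and all changed 4-fold or 8-fold were found.

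**Figure D2:**
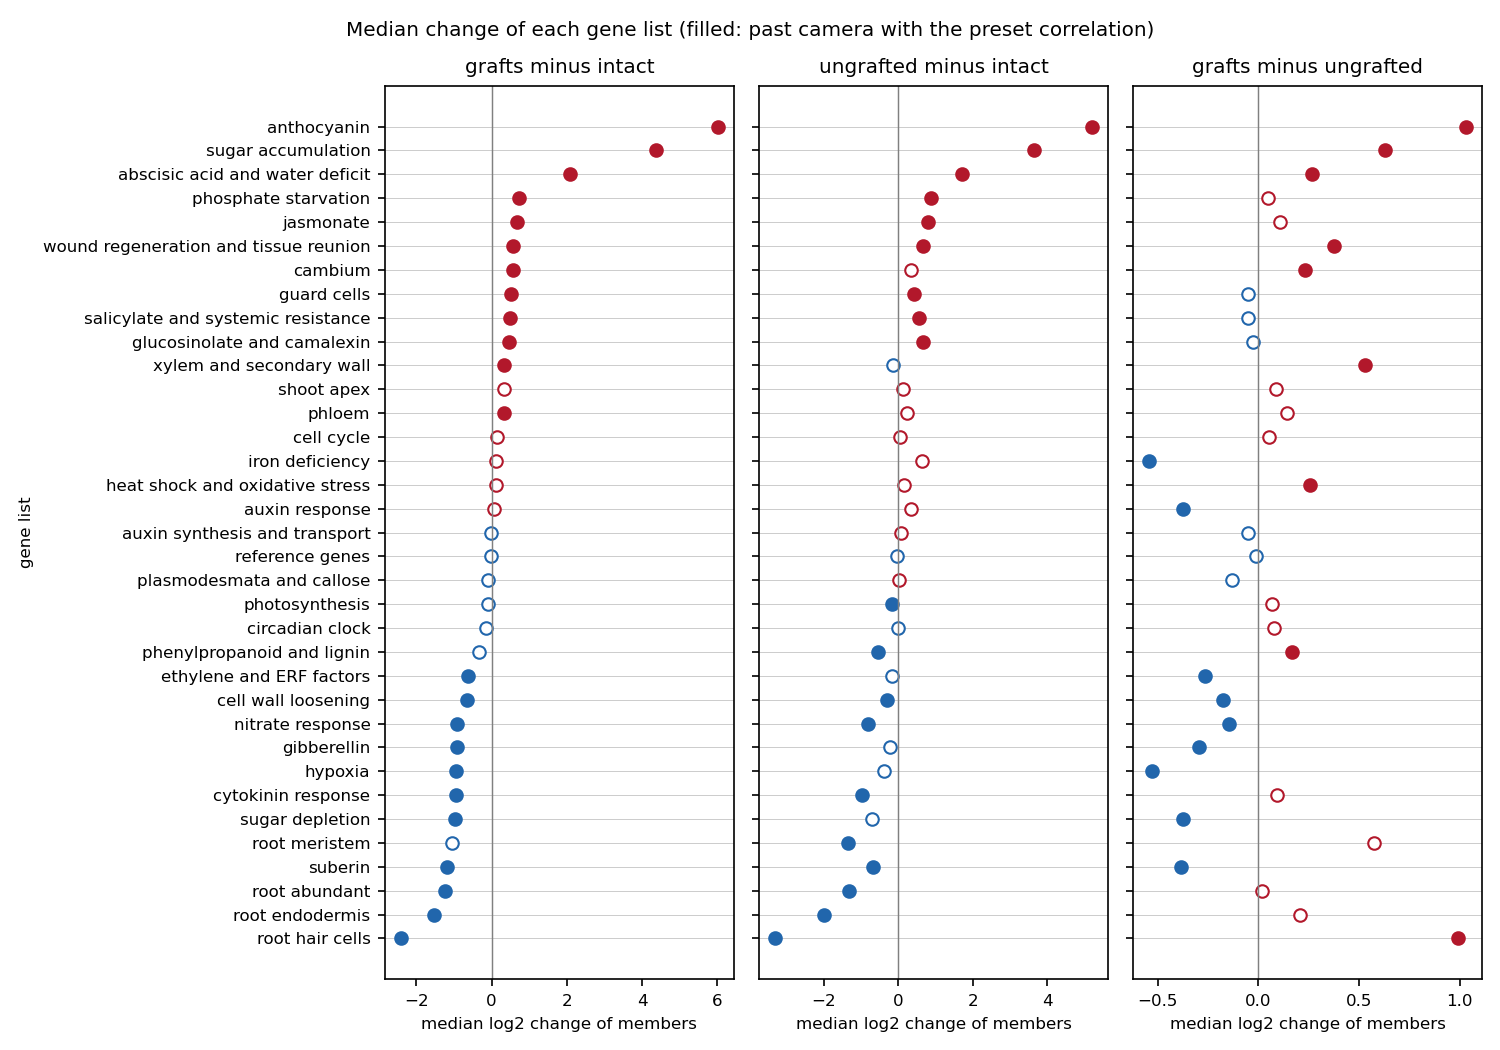
Median log2 difference of the members of each of 35 gene lists in the 3 comparisons, with filled symbols where camera with its preset correlation called the list. Anthocyanin and sugar accumulation lists lie farthest above 0 and root hair markers farthest below 0 against intact seedlings, while differences between grafts and ungrafted parts are smaller.

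The second comparison, ungrafted parts against intact seedlings, takes the cut without rejoining. Among genes above background in both groups, the largest rises were again LTP4 (8.62 ± 0.72, above background on 1 of 4 intact arrays) and the anthocyanin genes DFR (6.88 ± 0.37), LDOX (5.81 ± 0.3, above background on 3 of 4 intact arrays) and UF3GT (5.78 ± 0.35) with PAP1 (6.57 ± 0.57, above background on 1 of 4 intact arrays), and AT1G80130 (6.84 ± 0.22). The deepest such fall was in AGP30 (-9.26 ± 0.85, above background on 1 of 3 ungrafted arrays), a root cell wall protein gene, followed by AT1G52060 (-8.23 ± 0.55, above background on 1 of 3 ungrafted arrays) and AT5G42510 (-6.62 ± 0.48, above background on 1 of 3 ungrafted arrays) and by AT5G62340 (-6.37 ± 0.3), AT4G14060 (-6.13 ± 0.37) and AT5G54370 (-6.05 ± 0.22). Adjusted p for these 12 genes ran from 2.85e-07 to 3.59e-05, with n = 3 per group and no overlap between the groups.

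Of the 10 anthocyanin genes 7 rose and 2 fell (10 adjusted over the list), with TT8 (4.08 ± 0.26) among the rises. Anthocyanin genes had median 5.2 [4.62 to 5.71], adjusted p = 3.73e-04, and 0.328 with an estimated correlation. With PAP2 at its bound of at least 10.7-fold the median was 4.65. All 6 sugar accumulation genes rose (6 adjusted over the list), as in BAM5 (5.41 ± 0.31, above background on 2 of 4 intact arrays), GBSS1 (4.2 ± 0.15), APL3 (3.1 ± 0.17) and TPS5 (2.02 ± 0.16). Sugar accumulation genes had median 3.65 [3.44 to 3.9], adjusted p = 1.31e-05, and 0.210 with an estimated correlation. Of 20 abscisic acid and water deficit genes 15 rose (15 adjusted over the list), such as COR15A (5.66 ± 0.39), LTP3 (5.23 ± 0.35), RD20 (4.31 ± 0.31) and COR15B (3.85 ± 0.24). These water deficit genes had median 1.72 [1.55 to 1.73], adjusted p = 8.96e-08, and 0.292 with an estimated correlation. Of 27 jasmonate genes 15 rose and 1 fell (17 adjusted over the list). Jasmonate genes had median 0.79 [0.77 to 1.07], adjusted p = 8.79e-05, and 0.350 with an estimated correlation. AOC1 (2.87 ± 0.18), LOX2 (2.82 ± 0.18), VSP2 (2.73 ± 0.28), AOS (1.6 ± 0.08) and JAZ10 (0.75 ± 0.2) rose. Of 16 salicylate genes 8 rose and 2 fell (14 adjusted over the list). Salicylate genes had median 0.56 [0.58 to 0.72], adjusted p = 0.0145, and 0.462 with an estimated correlation. PR2 (2.74 ± 0.4), FMO1 (2.19 ± 0.36) and WRKY62 (1.44 ± 0.16, above background on 1 of 4 intact arrays) rose and EDS5 (-0.65 ± 0.08) fell. Of 20 glucosinolate and camalexin genes 12 rose (13 adjusted over the list), such as CYP79F1 (2.3 ± 0.23), CYP71A13 (1.62 ± 0.19), MAM1 (0.85 ± 0.1) and SUR1 (0.7 ± 0.09). Glucosinolate genes had median 0.67 [0.59 to 0.65], adjusted p = 6.90e-04, and 0.328 with an estimated correlation. Of 11 phosphate starvation genes 7 rose and 1 fell (9 adjusted over the list). Phosphate genes had median 0.89 [0.9 to 0.94], adjusted p = 0.0198, and 0.328 with an estimated correlation. PAP17 (2.66 ± 0.29), MGD3 (1.4 ± 0.14) and MGD2 (0.89 ± 0.1) rose and RNS1 (-2.15 ± 0.2) fell. Of 8 guard cell genes 7 rose (7 adjusted over the list), such as MUTE (0.83 ± 0.19), KAT1 (0.71 ± 0.08), FAMA (0.42 ± 0.11) and MYB60 (0.41 ± 0.12). Guard cell genes had median 0.42 [0.44 to 0.55], adjusted p = 0.00839, and 0.328 with an estimated correlation.

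Of 17 wound regeneration and reunion genes 11 rose and 2 fell (13 adjusted over the list). Wound genes had median 0.67 [0.57 to 0.8], adjusted p = 0.00466, and 0.328 with an estimated correlation. ANAC071 (3.58 ± 0.13), RAP2.6L (1.73 ± 0.14), PLT7 (1.69 ± 0.14, above background on 2 of 4 intact arrays), HCA2 (0.67 ± 0.13) and WIND1 (0.54 ± 0.13) rose and XTH20 (-1.92 ± 0.11) fell. ERF115, above background on 2 of 3 ungrafted arrays and on none of intact seedlings, was at least 1.09-fold higher (adjusted p = 0.00192). With it at that bound the wound median was 0.54. Vascular lists did not pass: 3 of 9 phloem genes rose and 1 fell (median 0.24 [0.2 to 0.28], 4 adjusted over the list, adjusted p = 0.218), 1 of 13 xylem and secondary wall genes rose and 3 fell (median -0.14 [-0.49 to 0.07], 4 adjusted over the list, adjusted p = 0.270), and 3 of 9 cambium genes rose and 1 fell (median 0.33 [0.13 to 0.51], 5 adjusted over the list, adjusted p = 0.176). PP2-A1 (1.19 ± 0.09), APL (0.69 ± 0.09), NEN4 (0.5 ± 0.14), MYB83 (0.6 ± 0.12), CLE44 (1.03 ± 0.18), CLE41 (0.8 ± 0.2) and LHW (0.52 ± 0.09) rose. XCP1 (-1.35 ± 0.14), IRX6 (-0.51 ± 0.11), LAC17 (-0.51 ± 0.12), SEOR1 (-0.47 ± 0.09) and TMO5 (-0.35 ± 0.09) fell. Of 31 cell cycle genes 4 rose and 1 fell (median 0.06 [0.13 to 0.21], 3 adjusted over the list, adjusted p = 0.389), with TSO2 (1.12 ± 0.16), RNR2A (0.55 ± 0.11) and CYCD3;1 (0.37 ± 0.12) and CDC6 (-1.57 ± 0.12). Of 24 auxin response genes 8 rose and 3 fell (median 0.35 [0.16 to 0.37], 12 adjusted over the list, adjusted p = 0.0786), with LBD17 (1.79 ± 0.14), LBD16 (1.59 ± 0.37), IAA20 (1.52 ± 0.16), GH3.5 (1.44 ± 0.21) and LBD18 (0.93 ± 0.13), while GH3.3 measured 0.61 ± 0.35 (adjusted p = 0.204). Of 25 auxin synthesis and transport genes 3 rose and 5 fell (median 0.08 [0.00 to 0.03], 8 adjusted over the list, adjusted p = 0.833), with a negative mean and test. PID (1.16 ± 0.09) rose, while PIN2 (-2.53 ± 0.2), YUC3 (-1.34 ± 0.18) and ABCB4 (-1.16 ± 0.12) fell. ALF4 rose by 0.28 ± 0.08 (adjusted p = 0.0299).

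Of 18 cytokinin genes 13 fell and 1 rose (15 adjusted over the list), such as ARR15 (-2.53 ± 0.2), ARR7 (-2.02 ± 0.21), IPT5 (-2.0 ± 0.18) and ARR4 (-1.7 ± 0.15). Cytokinin genes had median -0.96 [-0.99 to -0.88], adjusted p = 1.43e-05, and 0.213 with an estimated correlation. Of 9 nitrate response genes 7 fell (8 adjusted over the list), such as NRT2.1 (-2.54 ± 0.22), NIA1 (-2.12 ± 0.18), LBD39 (-1.57 ± 0.14) and NIR1 (-0.66 ± 0.13). Nitrate genes had median -0.81 [-1.06 to -0.7], adjusted p = 3.73e-04, and 0.328 with an estimated correlation. Of 15 phenylpropanoid and lignin genes 10 fell and 2 rose (13 adjusted over the list). Phenylpropanoid genes had median -0.53 [-0.6 to -0.49], adjusted p = 0.0115, and 0.328 with an estimated correlation. CAD4 (-1.09 ± 0.11), CYP98A3 (-1.0 ± 0.09) and PAL1 (-0.89 ± 0.11) fell and FAH1 (1.03 ± 0.1) rose. Of 9 suberin genes 8 fell (8 adjusted over the list), such as FAR5 (-1.61 ± 0.11), ASFT (-1.19 ± 0.18), CYP86B1 (-1.05 ± 0.15) and CYP86A1 (-1.01 ± 0.15). Suberin genes had median -0.68 [-0.82 to -0.71], adjusted p = 7.90e-04, and 0.328 with an estimated correlation. Of 29 cell wall loosening genes 14 fell and 6 rose (20 adjusted over the list). Cell wall genes had median -0.3 [-0.5 to -0.33], adjusted p = 0.0405, and 0.350 with an estimated correlation. PGX1 (-3.93 ± 0.31) and XTH18 (-1.93 ± 0.19) fell and EXPA3 (1.14 ± 0.09) rose, and the list lost its call without intact 1 (0.0665), with 0.0175 to 0.0665 over its alternatives. Of 26 photosynthesis genes 4 fell (2 adjusted over the list). Photosynthesis genes had median -0.16 [-0.23 to -0.12], adjusted p = 0.0136, and 0.558 with an estimated correlation. The 4 that fell were RBCS2B (-0.53 ± 0.09), PETC (-0.5 ± 0.1), RBCS1B (-0.36 ± 0.12) and GAPB (-0.32 ± 0.1). This list lost its call with quantile normalization (median -0.04, adjusted p = 0.326), with normexp correction before it (-0.02, 0.377) and in the deposited value table (-0.04, 0.325), with 3.38e-04 to 0.377 over its alternatives. RBCS1B and GAPB lost theirs under the same 3 settings, and RBCS1B with slide or replicate number as a block.

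Root markers fell here too. All 8 root hair genes fell (8 adjusted over the list), including MRH6 (-4.42 ± 0.16), COBL9 (-3.92 ± 0.16), PRP3 (-3.67 ± 0.15) and LRX1 (-2.94 ± 0.13). Root hair genes had median -3.3 [-3.61 to -3.21], adjusted p = 3.39e-08, and 0.213 with an estimated correlation. Of 7 endodermis genes 6 fell (6 adjusted over the list), such as CASP1 (-2.21 ± 0.2), CASP5 (-1.98 ± 0.19) and CASP4 (-1.89 ± 0.14). Endodermis genes had median -1.98 [-2.08 to -1.93], adjusted p = 3.73e-04, and 0.328 with an estimated correlation. Of 5 root meristem genes 4 fell (4 adjusted over the list). Root meristem genes had median -1.35 [-1.4 to -1.25], adjusted p = 0.0123, and 0.328 with an estimated correlation. The 4 that fell were RGF3 (-2.17 ± 0.21), PLT2 (-1.76 ± 0.27) and RGF2 (-1.33 ± 0.14) as well as PLT1 (-1.35 ± 0.17, above background on 1 of 3 ungrafted arrays). All 7 root abundant genes fell (7 adjusted over the list), such as TIP2;3 (-3.68 ± 0.31), TIP4;1 (-3.35 ± 0.14) and PHT1;1 (-1.27 ± 0.15). Root abundant genes had median -1.31 [-1.53 to -1.32], adjusted p = 3.26e-05, and 0.210 with an estimated correlation. Intact replicate 1, at -0.37 in the 5' measure, is in the reference group of these shifts too. Lists not past the test were hypoxia with 6 down and 1 up of 11 (median -0.39 [-0.6 to -0.42], 8 adjusted over the list, adjusted p = 0.0542), sugar depletion with 5 down and 1 up of 10 (median -0.7 [-0.84 to -0.58], 8 adjusted over the list, adjusted p = 0.0587), gibberellin with 4 down and 2 up of 12 (median -0.22 [-0.55 to -0.26], 7 adjusted over the list, adjusted p = 0.218) and ethylene with 5 down and 3 up of 23 (median -0.16 [-0.27 to -0.1], 8 adjusted over the list, adjusted p = 0.473). Iron deficiency had 6 up and 2 down of 10 (median 0.65 [0.33 to 0.68], 9 adjusted over the list, adjusted p = 0.218, with a mean of -0.02 and a test towards higher values), and heat shock 2 up and 3 down of 10 (median 0.15 [-0.32 to 0.13], 5 adjusted over the list, adjusted p = 0.659, with a negative mean and test). Plasmodesmata genes had 2 up and 1 down of 6 (median 0.03 [-0.01 to 0.04], 3 adjusted over the list, adjusted p = 0.625), shoot apex genes 3 up and 1 down of 7 (median 0.12 [0.13 to 0.43], 4 adjusted over the list, adjusted p = 0.283), clock genes 3 up and 3 down of 12 (median -0.01 [-0.06 to 0.03], 6 adjusted over the list, adjusted p = 0.823, with a positive mean) and reference genes 1 down of 6 (median -0.03 [-0.12 to 0.02], 1 adjusted over the list, adjusted p = 0.648). Without single samples sugar depletion passed (grafts 2 0.0451, ungrafted 3 0.0264, intact 2 0.0383), as did hypoxia (grafts 2 0.0456, ungrafted 1 0.0342) and auxin response (ungrafted 2 0.0398). With slide as a block sugar depletion (0.0145), hypoxia (0.0304) and cell cycle (0.0492) passed, and sugar depletion with the replicate number as a block (0.0192). In all hypoxia passed in 11 of 24 alternatives (0.0175 to 0.0856) and sugar depletion in 7 (0.0145 to 0.112).

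By limma 7872 genes changed between ungrafted parts and intact seedlings (3868 higher and 4004 lower, 1152 and 1667 by 2-fold or more), and groups did not overlap for 48.1% of genes against 10% by chance. Camera called 19 lists with its preset correlation. No list was called with an estimated correlation (5 at an unadjusted p under 0.05) and fry called 27. In simulated data with ungrafted parts changed, 48.0% of genes changed 1.5-fold, 86.0% of those changed 2-fold and all changed 4-fold or 8-fold were found. Of the 113 named genes past the test 104 stayed past it whichever sample was left out. The others were GAPB, RBCS1B, CYCD3;1, NEN4, TMO5, FAMA, MYB60, JAZ10 and ALF4, whose adjusted p then reached up to 0.133. GH3.3 passed without intact 1 (0.0224) or with the replicate number as a block (0.0133).

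The responses of grafts and ungrafted parts against intact seedlings were alike across genes. DFR and LTP4 rose and MRH6 and TIP4;1 fell in both, and 3169 genes rose in both where 774 would be shared by independent lists of these sizes, while 3497 fell in both where 901 would. Another 21 genes went in opposite directions, against 1671 by independent lists, and 15 of the 21 lost a call when 1 sample was left out. Pearson's r across genes was 0.932 and Spearman's rho 0.876, and 84.7% of genes had the same sign. These are values across genes, which are not independent replicates. In 100 simulations of unchanged groups against the same intact samples they were 0.501, 0.468 and 66.7%. The covariance was 0.786 against 0.0154 simulated, a difference of 0.771. The 3 intact samples cannot be split into 2 sets of at least 2, so part of the excess can come from the shared controls.

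**Figure D3:**
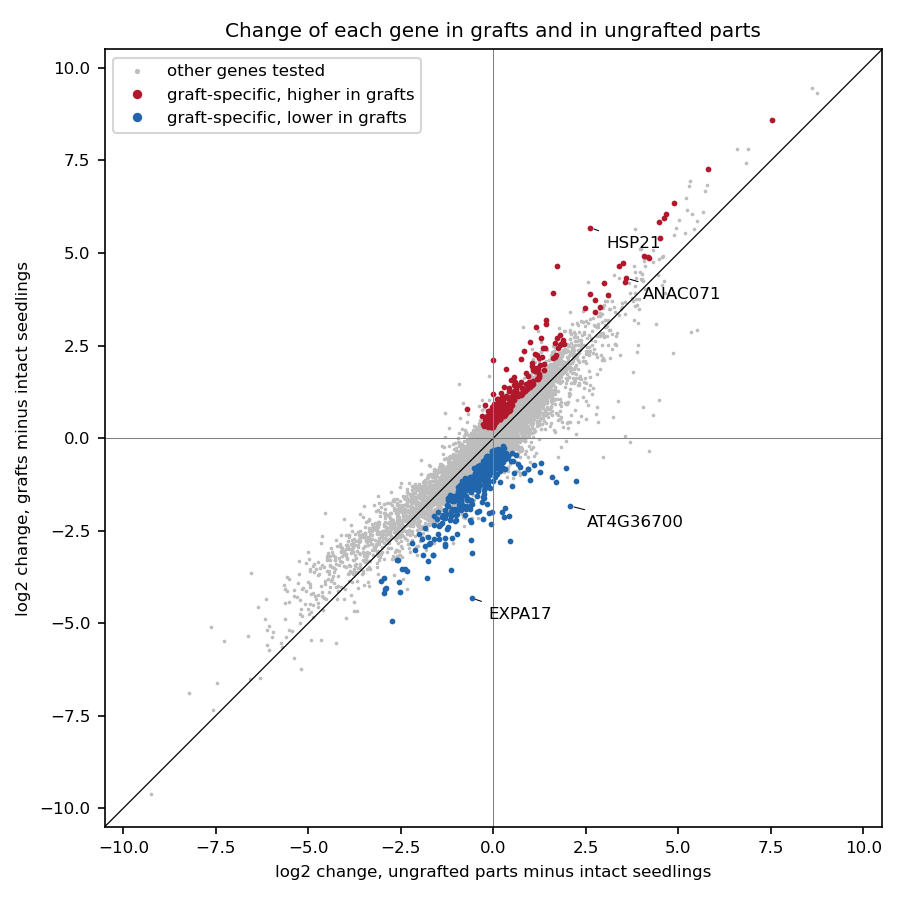
Log2 difference from intact seedlings for each gene in ungrafted parts (one axis) and in grafts (the other), with genes higher or lower specifically in grafts in colour and the line of equal change drawn. Most genes lie along the line, and HSP21, ANAC071, AT4G36700 and EXPA17 are labelled.

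The third comparison, grafts against ungrafted parts, sets rejoined against separated parts after the same cut. Among genes above background in both groups, the largest rises included the heat shock genes HSP21 (3.08 ± 0.44), whose protein acts in chloroplasts, and HSP18.2 (1.84 ± 0.35), and the chloroplast protease gene FTSH6 (2.93 ± 0.51). AT5G04380 (2.3 ± 0.47, above background on 1 of 3 ungrafted arrays), AT4G08570 (2.14 ± 0.25) and PRP1 (1.93 ± 0.2), a cell wall protein gene, rose as well. The largest such falls were AT4G36700 (-3.91 ± 0.34), EXPA17 (-3.73 ± 0.11) and AT1G28160 (-3.71 ± 0.66, above background on 1 of 3 grafts arrays) and PRX52 (-3.45 ± 0.33), AT2G16190 (-3.2 ± 0.42) and AT4G25580 (-2.87 ± 0.33, above background on 2 of 3 grafts arrays), where EXPA17 is an expansin and PRX52 a peroxidase gene. Adjusted p for these 12 genes ran from 1.96e-06 to 0.0370 (n = 3 per group), with no overlap between groups. Of the 45 named genes past this test, 13 stayed past it whichever of the 9 samples was left out: AT4G08570, PRP1, AT4G36700, EXPA17, PRX52, AT4G25580, GASA1, PRP3, EXPA18, AT2G16190, HSP21, RAP2.6L and GA2OX2. Left out singly, grafts 1, 2 and 3 ended 19, 25 and 26 of the 45 calls, ungrafted 1, 2 and 3 ended 26, 8 and 27, and intact 2 and 3 ended 10 and 9. With the 5' measure as a covariate 27 of the 45 calls remained, and with no filter on dim probes 21 ended. Without slide 1 only 12 remained, and HSP21, RAP2.6L and GA2OX2 were among the 33 that ended. In every alternative, stricter thresholds included, 9 remained. The probes of EXPA17 (AT4G01630) and AT4G36700 lie on chromosome 4 at 701449 to 701508 and 17298663 to 17298722 (ath1:Jan2004).

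The xylem list was called higher in grafts. Of 13 xylem and secondary wall genes 6 rose (13 adjusted over the list), such as the xylem proteases XCP1 (0.79 ± 0.14) and XCP2 (0.54 ± 0.11), the vessel master regulator gene VND7 (0.69 ± 0.14) and IRX6 (0.69 ± 0.11). Xylem genes had median 0.53 [0.4 to 0.65], adjusted p = 1.38e-10, and 0.340 with an estimated correlation. With the replicate number as a block VND7 and XCP2 did not pass, and with slide as a block XCP2 did not. Of 17 wound regeneration and reunion genes 3 rose and 1 fell (7 adjusted over the list). Wound genes had median 0.38 [0.11 to 0.55], adjusted p = 1.81e-04, and 0.340 with an estimated correlation. ANAC071 (0.74 ± 0.13), TMO6 (0.55 ± 0.12) and XTH20 (0.53 ± 0.11) rose, and RAP2.6L, which with ANAC071 is known from cut stems, fell (-1.23 ± 0.14). With slide as a block XTH20 did not pass. ERF115 (1.34 ± 0.36, above background on 2 of 3 ungrafted arrays), HCA2 (0.21 ± 0.13), WIND1 (-0.11 ± 0.13) and ALF4 (0.04 ± 0.08) did not pass. Of 9 cambium genes none passed limma's test (3 at an unadjusted p under 0.05), while the list had median 0.23 [0.12 to 0.34], adjusted p = 0.0241, and 0.360 with an estimated correlation. Values were MP (0.4 ± 0.12), TMO5 (0.25 ± 0.09), ATHB8 (0.24 ± 0.09) and CLE41 (0.31 ± 0.2). The cambium list lost its call without grafts 1 (0.0631) or ungrafted 3 (0.0838), with 0.0161 to 0.186 over its alternatives. Of 9 phloem genes none passed limma's test or had an unadjusted p under 0.05 (median 0.14 [0.05 to 0.31], 0 adjusted over the list, adjusted p = 0.112), with SEOR2 (0.21 ± 0.11), SEOR1 (0.17 ± 0.09), CALS7 (0.16 ± 0.12) and NEN4 (0.18 ± 0.14). Of 31 cell cycle genes none passed limma's test (2 at an unadjusted p under 0.05, median 0.05 [-0.06 to 0.14], 0 adjusted over the list, adjusted p = 0.501), with CYCD3;1 (0.39 ± 0.12), CDC6 (-0.34 ± 0.12), MCM2 (0.2 ± 0.1) and PCNA2 (0.19 ± 0.15).

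The auxin response list was called lower in grafts than in ungrafted parts, and 5 of 24 genes fell (9 adjusted over the list). Auxin response genes had median -0.37 [-0.63 to -0.08], adjusted p = 0.00159, and 0.467 with an estimated correlation. Among those that fell, LBD29, not well above background in grafts, was at least 1.95-fold lower (adjusted p = 0.0165), and IAA6 (-1.36 ± 0.27), LBD18 (-0.73 ± 0.13) and LBD17 (-0.73 ± 0.14) fell, while GH3.3 (-1.51 ± 0.35) and LBD16 (-0.96 ± 0.37) did not pass. Of 25 genes of auxin synthesis and transport none passed limma's test (7 at an unadjusted p under 0.05, median -0.05 [-0.14 to 0.03], 0 adjusted over the list, adjusted p = 0.972, with a positive mean and test), with PIN2 (0.84 ± 0.2), LAX2 (0.37 ± 0.11) and PIN6 (0.45 ± 0.16). Of 12 gibberellin genes 2 fell (5 adjusted over the list). Gibberellin genes had median -0.3 [-0.62 to -0.15], adjusted p = 0.0171, and 0.350 with an estimated correlation. The 2 that fell were GASA1, a gibberellin-regulated peptide gene, and the inactivating oxidase gene GA2OX2 (-1.9 ± 0.16 and -1.14 ± 0.12), while GASA6 (-1.04 ± 0.26) and GA3OX2 (1.16 ± 0.34) did not pass. Of 29 cell wall loosening genes 5 fell and 1 rose (11 adjusted over the list). Cell wall genes had median -0.18 [-0.28 to -0.17], adjusted p = 0.0147, and 0.360 with an estimated correlation. Besides EXPA17, EXPA14 (-0.82 ± 0.17) fell, and the polygalacturonase gene ADPG2, not well above background in grafts, was at least 1.28-fold lower. Of 23 ethylene and ERF genes 1 rose, ERF2 (0.71 ± 0.14) (7 adjusted over the list). Ethylene genes had median -0.26 [-0.48 to -0.09], adjusted p = 0.0171, and 0.386 with an estimated correlation. ACO1 (0.41 ± 0.1), ACS7 (-0.91 ± 0.23) and ACS2 (-0.86 ± 0.23) did not pass, and the ethylene list lost its call without ungrafted 1 (0.0686), with 0.00214 to 0.111 over its alternatives. ERF2 and EXPA14 did not pass with the replicate number as a block, nor ERF2 and LBD17 with slide as a block. Ratios of 5' to 3' signal differed between these groups on slides 1 and 3, and with that measure as a covariate the ethylene (0.111), gibberellin (0.0817), cell wall (0.0694) and cambium (0.186) lists did not pass, while jasmonate (7.83e-04), endodermis (0.0193) and photosynthesis (0.0308) did.

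Anthocyanin, root hair and 4 other lists were called higher in grafts. Of 10 anthocyanin genes 3 rose (8 adjusted over the list), LDOX (1.47 ± 0.3), F3'H (1.09 ± 0.22) and F3H (1.0 ± 0.16). Anthocyanin genes had median 1.03 [0.94 to 1.1], adjusted p = 8.47e-07, and 0.340 with an estimated correlation, while CHS measured 0.69 ± 0.17. Of 6 sugar accumulation genes none passed limma's test (4 at an unadjusted p under 0.05, 4 adjusted over the list). Sugar accumulation genes had median 0.63 [0.51 to 0.68], adjusted p = 8.20e-04, and 0.340 with an estimated correlation. Values were APL3 (0.77 ± 0.17), GBSS1 (0.68 ± 0.15), SUS3 (0.58 ± 0.14) and TPS5 (0.48 ± 0.16). Of 20 abscisic acid and water deficit genes 1 rose, P5CS1 (0.91 ± 0.16) (2 adjusted over the list). These water deficit genes had median 0.27 [0.23 to 0.29], adjusted p = 0.0179, and 0.467 with an estimated correlation, beside RD22 (0.51 ± 0.12), LTP3 (0.93 ± 0.35) and PP2CA (0.33 ± 0.13). That list lost its call without grafts 1 (0.179) or ungrafted 2 (0.0911), with 6.08e-04 to 0.179 over its alternatives. Of 10 heat shock and oxidative stress genes 2 rose (5 adjusted over the list), HSP18.2 and GSTU25 (0.86 ± 0.17). Heat shock genes had median 0.26 [-0.04 to 0.45], adjusted p = 0.0322, and 0.492 with an estimated correlation, with a negative median on slide 1. APX2 (2.19 ± 0.62, above background on 2 of 3 ungrafted arrays) and HSP17.6A (1.08 ± 0.34) did not pass. The heat shock list lost its call without grafts 3 (0.0664), ungrafted 2 (0.203) or intact 1 (0.0708) or with probes above background on all arrays alone (0.191), with 7.12e-04 to 0.203 over its alternatives. Of 15 phenylpropanoid and lignin genes none passed limma's test (1 at an unadjusted p under 0.05, 0 adjusted over the list). Phenylpropanoid genes had median 0.17 [0.11 to 0.21], adjusted p = 0.00564, and 0.360 with an estimated correlation. Members measured CYP98A3 (0.3 ± 0.09), HCT (0.27 ± 0.12), 4CL1 (0.26 ± 0.11) and PAL4 (0.24 ± 0.12). Of 8 root hair genes 6 rose (7 adjusted over the list), such as EXPA18 (1.36 ± 0.19), PRP3 (1.11 ± 0.15), MRH6 (1.11 ± 0.16) and COBL9 (0.97 ± 0.16). Root hair genes had median 0.99 [0.63 to 1.2], adjusted p = 1.56e-08, and 0.340 with an estimated correlation.

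Lists of sugar depletion, iron, nitrate, hypoxia and suberin were called lower in grafts. Of 10 sugar depletion genes none passed limma's test (7 at an unadjusted p under 0.05, 6 adjusted over the list). Sugar depletion genes had median -0.37 [-0.46 to -0.33], adjusted p = 2.59e-04, and 0.386 with an estimated correlation. Values were BGLU30 (-1.32 ± 0.33), DIN1 (-1.09 ± 0.29), ASN1 (-0.78 ± 0.22) and TPS9 (-0.3 ± 0.1). Of 10 iron deficiency genes none passed limma's test (6 at an unadjusted p under 0.05, 5 adjusted over the list). Iron genes had median -0.54 [-0.77 to -0.32], adjusted p = 8.20e-04, and 0.360 with an estimated correlation. Members measured BHLH100 (-1.3 ± 0.34), BHLH39 (-0.94 ± 0.29), BHLH38 (-0.89 ± 0.29) and FRO3 (-0.52 ± 0.18). With IRT1, above background in no graft, at no change, the iron median was -0.5. Of 9 nitrate response genes 2 fell, NRT2.1 (-1.36 ± 0.22) and NRT1.1 (-0.59 ± 0.12) (2 adjusted over the list). Nitrate genes had median -0.15 [-0.6 to 0.02], adjusted p = 0.0241, and 0.454 with an estimated correlation, with a positive median on slide 2. NIA1 (-0.52 ± 0.18) and LBD38 (-0.26 ± 0.15) did not pass. The nitrate list lost its call without grafts 1 (0.194) or ungrafted 3 (0.0612), with 0.00115 to 0.261 over its alternatives, 0.160 with the 5' measure as a covariate and 0.0585 with quantile normalization. Of 11 hypoxia genes 5 fell and 1 rose (7 adjusted over the list). Hypoxia genes had median -0.53 [-0.53 to -0.37], adjusted p = 0.00995, and 0.340 with an estimated correlation. HB1 (-1.07 ± 0.18) and PCO1 (-0.95 ± 0.15) fell, HRE2, not well above background in grafts, was at least 1.90-fold lower, and PDC1 (0.54 ± 0.08) rose. Of 9 suberin genes 1 fell, FAR5 (-0.5 ± 0.11) (4 adjusted over the list). Suberin genes had median -0.38 [-0.44 to -0.28], adjusted p = 0.0265, and 0.454 with an estimated correlation, beside KCS2 (0.8 ± 0.19), GPAT7 (-0.59 ± 0.16) and GPAT5 (-0.43 ± 0.15). The suberin list lost its call without grafts 2 (0.110), ungrafted 1 (0.0686), ungrafted 3 (0.0675) or intact 1 (0.0563), with 0.00700 to 0.110 over its alternatives, and 0.0553 with the 5' measure as a covariate. FAR5 did not pass with slide as a block.

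Among lists not past the test, cytokinin genes had 1 up and 3 down of 18 (median 0.09 [0.00 to 0.23], 5 adjusted over the list, adjusted p = 0.930, with a negative mean), root meristem genes 1 up of 5 (median 0.57 [0.38 to 0.84], 3 adjusted over the list, adjusted p = 0.0894), root abundant genes 1 up and 1 down of 7 (median 0.02 [-0.22 to 0.21], 2 adjusted over the list, adjusted p = 0.974, with a negative mean), phosphate genes 1 down of 11 (median 0.05 [-0.24 to 0.12], 1 adjusted over the list, adjusted p = 0.856, with a negative mean and test) and clock genes 1 up of 12 (median 0.08 [-0.02 to 0.09], 4 adjusted over the list, adjusted p = 0.199). No gene passed limma's test in the following, where counts at an unadjusted p under 0.05 are given first. They were 3 of 27 jasmonate genes (median 0.11 [-0.04 to 0.23], 0 adjusted over the list, adjusted p = 0.0709), with VSP2 (0.32 ± 0.28) and JAZ10 (-0.24 ± 0.2), 2 of 16 salicylate genes (median -0.05 [-0.29 to 0.14], 0 adjusted over the list, adjusted p = 0.564), 6 of 20 glucosinolate genes (median -0.03 [-0.31 to 0.17], 5 adjusted over the list, adjusted p = 0.199) and 1 of 26 photosynthesis genes (median 0.07 [-0.04 to 0.15], 0 adjusted over the list, adjusted p = 0.0758). They were further 1 of 6 plasmodesmata genes (median -0.13 [-0.17 to -0.07], 1 adjusted over the list, adjusted p = 0.724), 2 of 7 endodermis genes (median 0.21 [-0.17 to 0.51], 0 adjusted over the list, adjusted p = 0.0696) and 2 of 8 guard cell genes (median -0.05 [-0.09 to -0.04], 0 adjusted over the list, adjusted p = 0.547). Of 7 shoot apex genes (median 0.09 [0.03 to 0.16], 0 adjusted over the list, adjusted p = 0.287) and 6 reference genes (median -0.01 [-0.18 to 0.06], 0 adjusted over the list, adjusted p = 0.907) no member had such a p. Left-out samples brought calls for jasmonate (grafts 1 0.00395, ungrafted 3 0.0400), endodermis (grafts 1 0.0105, ungrafted 1 0.0378, ungrafted 3 0.0429, intact 2 0.0354) and photosynthesis (grafts 2 0.0357, ungrafted 1 0.00694). They also did for phloem (grafts 1 0.0472), cell cycle (ungrafted 2 0.0107), glucosinolate (grafts 3 0.0164) and root meristem (ungrafted 1 0.04996). Of 24 alternatives jasmonate passed in 10 (7.83e-04 to 0.330), endodermis in 7 (0.00491 to 0.295) and photosynthesis in 5 (2.01e-04 to 0.332).

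Between grafts and ungrafted parts 622 genes changed by limma (306 higher and 316 lower, 110 and 126 by 2-fold or more). Groups did not overlap for 28.9% of genes, where chance gives 10%. Without grafts 1, 2 or 3 the count was 357, 203 or 242, without ungrafted 1 or 3 it was 259 or 203, and without intact 1 it was 1096. Without slide 1, an alternative chosen after seeing the data, it was 124, and with the 5' measure as a covariate it was 573, of which 381 were among the 622. Without slide 1 the ethylene (0.0958), nitrate (0.261) and suberin (0.0599) lists did not pass, while jasmonate (0.00436), endodermis (0.00491), photosynthesis (0.0126), root meristem (0.0411), phloem (0.0437) and salicylate (0.0437) did. No list was called with an estimated correlation (3 at an unadjusted p under 0.05), and fry called 8. In simulated data with grafts changed, 36.0% of genes changed 1.5-fold, 84.0% of those changed 2-fold and all changed 4-fold or 8-fold were found.

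The design takes graft-specific genes in a 2-step order: first those that differ between grafts and intact seedlings, then, among these, those that differ between grafts and ungrafted parts in the same direction. Among genes above background on at least 1 array of all 3 groups, the largest graft-specific rises were HSP21, which rose by 5.69 against intact seedlings and 3.08 against ungrafted parts on the log2 scale, FTSH6 (4.64 and 2.93), HSP18.2 (2.99 and 1.84), AT4G08570 (2.12 and 2.14), CEL3 (3.08 and 1.66) and the sugar transporter gene STP11 (2.6 and 1.61). The largest such falls were AT4G36700 (-1.84 and -3.91), EXPA17 (-4.32 and -3.73), AT4G25580 (-1.18 and -2.87), PAP85 (-1.04 and -2.61), AT1G61840 (-3.11 and -2.54) and the dark-induced DIN11 (-2.12 and -2.53). Against ungrafted parts SEs were 0.26 for CEL3, 0.26 for STP11, 0.24 for PAP85, 0.58 for AT1G61840 and 0.21 for DIN11 (n = 3 per group). AT4G25580 was above background on 2 of 3 graft arrays and PAP85 and AT1G61840 on 1 of 3, and FTSH6 and STP11 were above background on 1 of 4 intact arrays. Second-step adjusted p ran from 8.35e-07 to 0.0271 for the 12 genes. AT1G61840 passed in this order alone (adjusted p = 0.0545 over all genes). Against ungrafted parts over all genes, CEL3 lost its call without grafts 2 or 3 and STP11 without grafts 1, 2 or 3, FTSH6 without grafts 3 (0.0637) or ungrafted 1 (0.0649), and HSP18.2 without grafts 3 (0.0907), ungrafted 1 (0.0744), ungrafted 2 (0.0617) or ungrafted 3 (0.0796). Over their alternatives p ran from 0.00597 to 0.0564 for CEL3, 0.0124 to 0.0652 for STP11, 0.00714 to 0.101 for FTSH6 and 0.0107 to 0.0967 for HSP18.2. Against intact seedlings AT4G25580 lost its call without grafts 2, intact 1 or intact 3 (0.000361 to 0.106 over its alternatives).

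In all 601 of the 9038 genes were graft-specific, 221 higher and 380 lower, while 314 differed from ungrafted parts in the direction opposite to that against intact seedlings. Of the 601 genes 320 also changed in ungrafted parts against intact seedlings, 299 of them in the same direction. With the replicate number as a block, which pairs grafts and ungrafted parts, 909 genes were graft-specific. Without grafts 1, 2 or 3 there were 365, 286 or 348, without ungrafted 1 or 3 there were 275 or 208, and without intact 1 there were 1101. Without slide 1 there were 180. In simulated data, 163 of 200 genes changed in grafts alone were recovered, with 6 other genes.

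**Figure D4:**
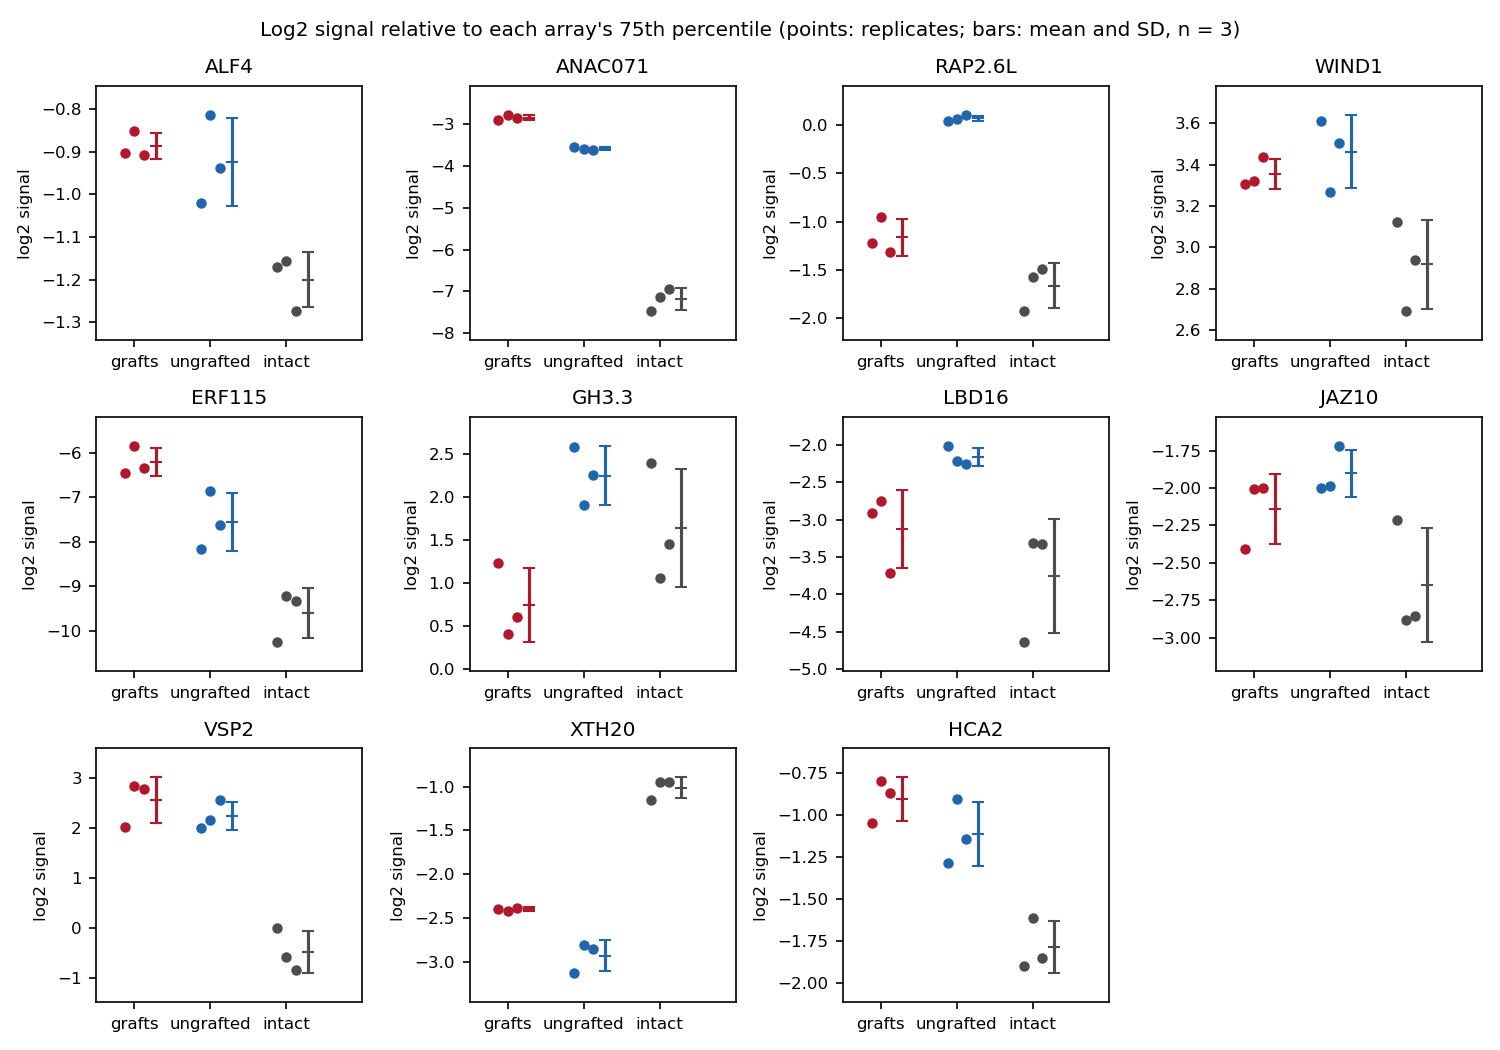
Normalised log2 signal of genes named in every comparison, with 1 point per replicate in grafts, ungrafted parts and intact seedlings, and bars for mean ± SD. ANAC071 and VSP2 are high in both cut groups, RAP2.6L is highest in ungrafted parts, and XTH20 is lower in both cut groups than in intact seedlings.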

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

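The slide, covariate and root-share tests and the clock test were chosen after seeing the results they bear on, and the probe and normalization tests of intact replicate 1 before.

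Genes that differ between grafts and ungrafted parts could reflect grafting or RNA quality, since the 5' measure parts these groups on slides 1 and 3 but not on slide 2. For genes called from slides 1 and 3 alone, the median change on slide 2 over that on slides 1 and 3 was 0.728 (95% interval 0.594 to 0.885) for 30 higher genes and 0.765 (0.622 to 0.907) for 60 lower genes. Of these 30 and 59 kept their sign on slide 2, but 1 pair of samples gives no spread and excludes nothing. For all 622 genes called the median change was 0.86 without and 0.85 with the 5' measure as a covariate. The ratio was 0.987 (0.902 to 1.02 with 1 sample left out). The covariate's slope comes from differences within groups, and the genes were called partly for small differences there, so this ratio cannot exclude RNA quality. With the covariate 381 (61.3%) passed. For the 241 others the median change went from 0.74 to 0.68 and the median SE from 0.15 to 0.17. RNA quality stays open, as a set and gene by gene.

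Root markers, lower against intact seedlings, could reflect a smaller share of root tissue in the samples or regulation within roots. A smaller share alone predicts equal shifts for 4 root lists only if markers and zones are equal, which was not tested. Members parted by list with permutation p = 0.0554 between grafts and intact seedlings, which leaves a share of tissue open there. The p was 0.0141 between ungrafted parts and intact seedlings and 0.00226 between grafts and ungrafted parts. In the latter, root hair genes had a median of 0.99 and root abundant genes 0.02. These values argue against an equal shift of the 4 lists in both, though the permutation treats genes as independent. A share of tissue with unequal markers or zones stays open.

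Intact replicate 1 could stand apart through RNA quality, array effects or time of day. Deviations at the 5' and 3' probe correlated with r = 0.270 (95% interval 0.234 to 0.306) against 0.410 for intact 2 minus 3, with medians of -0.47 and 0.05, which leaves RNA quality open. Quantile normalization left its differences at 1.90 times that between the others, so of array effects only the intensity distribution is excluded. The median deviation of 12 clock genes lay at percentile 78.6 of 10000 random lists, so sampling at another time stays open.

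Whether any grouping of the samples gives such counts was examined by splitting the 6 samples of a comparison 3 against 3 in all 10 ways, too few for a share below 0.05. For genes 1 of the 10 splits, the real one, reached the real count in each comparison, and the highest of the others was 0 by limma, with up to 2219, 1811 and 1386 genes at an unadjusted p under 0.05 in the 3 comparisons, in the report's order. For lists it was 1 split (23 against 17 at most), 2 splits (19 against 19) and 1 split (18 against 17). Each other split sets 2 samples of one group with 1 of the other, so its calls can hold part of the treatment. For graft-specific genes 1 of 100 drawn splits into 3 groups, the real one, reached 601, against 12 at most, but no other draw kept the intact samples together, so this decides nothing. With intact samples kept there are 20 assignments, too few for a share below 0.05. The real one gave 601 and the one with grafts and ungrafted parts exchanged 465. The 18 mixed ones, where the spread within groups is raised in the same way, gave 1 at most.

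A difference between groups singled out 21 genes, called in opposite directions against intact seedlings in grafts and ungrafted parts and past the test between these, but 15 of them lost a call against intact seedlings when 1 sample was left out. Among the 6 others AT4G36700 measured -1.84 in grafts and 2.07 in ungrafted parts, the AP2 factor gene PUCHI of lateral root formation -0.74 and 1.1, and GPAT1 -0.84 and 0.94. The other way went BGLU45 alone with 0.79 and -0.7, whose fall in ungrafted parts was called in 18 of 27 alternatives and not without ungrafted 2, ungrafted 3, intact 1 or intact 2 (adjusted p up to 0.0871). In 3 of the 21 no graft array was above background, which leaves their fall in grafts without a measured size. Signal in data outside the gene tests: of 3804 tested probes with no single locus, 859 changed between grafts and intact seedlings, 712 between ungrafted parts and intact seedlings and 2 between grafts and ungrafted parts.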

How the results depend on the processing

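No gene or list turned its sign with a call in any alternative, and the cause of the differences was not tested unless stated. Named genes stayed called or uncalled in 3220 of 3280, 2992 of 3093 and 2337 of 2715 values, in the report's order. In the third, 312 values from the 45 called genes lost their call, and 66 from others gained one. Lists stayed called or uncalled in 808, 814 and 781 of 839 values (27, 4 and 28 lost, 4, 21 and 30 gained). Graft-specific genes numbered 327 with the second step adjusted over all genes, 281 when also not past the test in ungrafted parts, 134 at 2-fold or more, 170 at adjusted p below 0.01, 909 with the replicate block, 909 with only the 2 groups of each step and 180 without slide 1. Between grafts and ungrafted parts 319 genes changed with no filter on dim probes, 236 at 2-fold or more, 141 at adjusted p below 0.01 and 124 without slide 1, and fry called 8 lists. Against intact seedlings 3131 (grafts) and 2819 (ungrafted parts) changed at 2-fold or more, and 5229 in ungrafted parts at adjusted p below 0.01. Stricter thresholds lower counts by construction. With an estimated correlation camera called 0 lists in each comparison. The similarity r was 0.905 with no filter and 0.912 with the 5' measure as a covariate. Leaving out 1 sample gave 7239 to 10231, 6282 to 8868 and 203 to 1096 changed genes, 20 to 24, 18 to 21 and 16 to 19 lists, 208 to 1101 graft-specific genes and r of 0.916 to 0.936. Numbers 1, 2 and 3 correlated with -0.22, 0.18 and 0.04 between grafts and intact seedlings and 0.04, 0.43 and 0.21 between ungrafted parts and intact seedlings, so equal numbers were not taken as pairs there, though numbers 2 and 3 also share a slide, and the block gave 9445 and 8205 changed genes. Between grafts and ungrafted parts the replicate block ended the calls of VND7 (0.0602), XCP2 (0.0517), EXPA14 (0.0685) and ERF2 (0.0579) and brought calls for RD22, GPAT7, DIN1, APL3, SUS3, APX2, HSP17.6A, ERF115 and GH3.3, and changed no other call of a named gene there. Slide as a block ended 5 calls of named genes there and brought 8. Both arrays of intact 3 entered with a correlation over the RNA sample could not be fitted and was not run. Signal over background limits dim genes.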

Other observations

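These genes were picked after their values were seen, from lists that did not pass or hold opposing members. The clock genes PRR9 (2.02), RVE8 (1.27), CCA1 (1.14) and LHY (1.08), which peak in the morning, rose between grafts and intact seedlings, each in 27 of 27 alternatives. The evening genes LUX (-0.69, in 26 of 27), TOC1 (-0.58, in 18 of 27) and GI (-0.35, in 23 of 27) fell, but so did RVE1 (-0.60, in 12 of 27), a morning gene. The iron uptake gene FRO2 fell by 3.33 in grafts and 3.35 in ungrafted parts, and the iron deficiency regulator genes BHLH100 and BHLH101 rose in ungrafted parts (1.81 and 1.40), each in 27 of 27 alternatives. The shoot meristem genes KNAT1 (1.00 and 0.94) and STM (0.78 and 0.70) rose in both cut groups. CUC2 of the same list fell (-0.47, in 23 of 27 alternatives, and -0.42, in 15 of 27). Of 2 plasmodesmata protein genes PDLP1 rose (1.26 and 0.81) and PDLP5 fell (-1.07 and -0.71), and the common reference gene ACT2 fell (-0.80 and -0.58). Between grafts and ungrafted parts the cytokinin synthesis gene CYP735A2 fell (-1.44, in 27 of 27 alternatives, adjusted p 0.00106 to 0.0473).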
